A study of Mus musculus with 2 samples.

How the data were processed

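MicroRNA-seq was done on total RNA, size-selected below 30 nucleotides per the labels, from single hindbrains of 2 newborn mice (strain B6NCrl, age 0 day). The labels name pup 1 and pup 3 as separate animals with biological replicate numbers 1 and 2. They also give both pups the same donor identifier and record no sex. Both libraries form 1 group, so no contrast between conditions was possible. P-values that compare the 2 libraries gene by gene cover counting error only. They hold no estimate of the spread between animals or preparations, and none between conditions.

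The authors deposited 1 table per library of whole-number read counts per miRNA gene, not normalized and not pooled. Per the text files deposited beside the tables, the assembly was mm10 and the genome annotation M4. The aligner and the counting program are not given in the sources used here. Each table holds 3 count columns, for reads on any strand, on the gene's own strand and on the opposite strand. The own-strand counts were used throughout, because small RNA adapters keep the strand. The first rows name no gene and give reads that did not map, matched several genomic places, lay in no feature or were ambiguous. They stayed out of library totals and tests. In pup 1 these were 17.7% unmapped, 37.9% at several places and 2.66% in no feature on either strand, of 12126529 reads in the table. In pup 3 they were 13.9%, 39.4% and 1.59% of 14316243 reads. No read was ambiguous in either. Own-strand gene counts were 40.5% and 43.6% of the reads in the tables. Opposite-strand counts were 3.02% and 3.39% of gene counts.

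Because reads at several genomic places are given to no gene, miRNA genes with near-identical copies can be undercounted. Counts are per gene and do not separate the mature arms of a precursor. Ligation and amplification favour some small RNA sequences over others, so a level of one miRNA gene against another also reflects capture, and only a gene's own values are comparable between the libraries.

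Gene IDs were matched without their version to GENCODE M21, which uses the GRCm38 assembly of mm10. Of the 1973 genes, 1894 matched, 1815 of them with the same version. The 79 without a match had 1 own-strand count in each pup. Of the 2207 miRNA genes in M21, 313 have no entry in the tables and are not in the own-strand comparisons. Symbols, positions, strand, host genes, and precursor GC content come from M21, and synonyms from the RefSeq gene table of the same assembly. A host gene is an annotated gene on the same strand that contains the miRNA gene, with exon where any of its exons overlaps and intron otherwise. A precursor was taken to share sequence where a stretch of 20 bases occurs in the precursor of another miRNA gene elsewhere in the genome.

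Levels are CPM, own-strand counts of a gene per 1000000 own-strand miRNA gene counts of its library. Detection was 2 CPM in both pups. The spread between pups was the square root of edgeR's common dispersion (estimateDisp with an intercept only, TMM scaling, genes kept by filterByExpr), with an interval from 100 bootstraps over genes. Genes that differ between the libraries were found with an exact binomial test on the counts against the ratio of TMM effective library sizes (1.16, pup 3 over pup 1), two-sided. It ran on genes with 10 or more counts in sum, with Benjamini-Hochberg adjustment, and calls needed an adjusted p under 0.05 and a 2-fold difference. Log2 differences of genes are on TMM effective library sizes, unlike the CPM, with a pseudocount of 1 CPM, and their SE is the counting error of the 2 counts. Fisher's exact test compared detection of each list with all other genes. Shifts of lists were placed among 10000 random lists matched on mean CPM in 10 classes of the detected genes. A permutation test of medians with 100000 resamples compared multi-copy with single-copy genes. Intervals for shares are exact Clopper-Pearson at 95%.

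The 24 gene lists, the tests, the thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The lists hold 277 symbols, of which 254 genes have an entry and 202 of these were detected. The rule names the 25 genes of highest mean CPM, up to 4 members of highest mean CPM per list, and up to 5 called genes per direction with a mean of at least 10 CPM. No gene called higher in pup 3 met the last condition. Genes named outside the rule are stated to have been chosen after their values were seen. List members with no entry are left out of the list values.

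The calling step was tested on simulated counts for the 508 tested genes of the comparison of the 2 libraries. With only counting error drawn, 77% of genes changed 3-fold were called in the right direction. So were 94% of those changed 5-fold, and 0% of unchanged genes were called. With the spread between pups added and no gene changed, a median of 22.5 genes were called in 20 runs. That spread was estimated from these same 2 libraries. Alternatives covered the detection level, the pseudocount, the filters, DESeq2 median-of-ratios size factors and library totals in place of TMM, counts regardless of strand, and each pup alone where 1 library gives a value. Alternatives added later were a GC correction, a background of genes with a Mir symbol, groups set by shared sequence, and opposite-strand reads given to the gene annotated there. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.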

Results

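MicroRNA-seq measured small RNAs of under 30 nucleotides in the hindbrain of newborn mice of strain B6NCrl at postnatal day 0. The series held 1 group of 2 libraries, each from the single hindbrain of a separate pup. Replicate 1 came from pup 1 and replicate 2 from pup 3. No second condition was present, so the questions open to these data were which microRNA (miRNA) genes the newborn hindbrain expressed, at what level, and how closely the 2 pups matched. The tables gave 1973 annotated miRNA genes, and the counts of reads on each gene's own strand summed to 4906127 in pup 1 and 6238680 in pup 3. All levels are in CPM (own-strand counts per 1000000 own-strand miRNA gene counts of the library), given as mean ± SD with n = 2 pups unless stated. A count of 0 allowed a level of up to 0.611 CPM in pup 1 and 0.481 CPM in pup 3, at 3 counts of the total. Intervals for shares of counts and such floors cover counting error only, not the spread between animals or preparations. They also take each read as a separate molecule.

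Mir99a had the highest own-strand count of the miRNA genes counted in the newborn hindbrain, at 146287 ± 23157 CPM, or 14.6% ± 2.32 of all miRNA gene counts. Mirlet7g followed at 60594 ± 6741 CPM, Mir126a at 51803 ± 5634 CPM, Mir487b at 48749.7 ± 7545 CPM and Mirlet7i at 42142 ± 3205 CPM. The let-7 miRNAs restrain proliferation and rise as neural progenitors differentiate, and Mir126a is the endothelial miRNA of the Egfl7 gene. Next came Mir130a, Mir10a, Mir335, Mir100 and Mir30e, between 28569.5 ± 885 CPM for Mir130a and 21246 ± 7429 CPM for Mir30e. Mir335 lies in an intron of the imprinted gene Mest and had 27018 ± 2349 CPM. The 10 most abundant genes took 45.2% of the counts in pup 1 (exact binomial 95% interval 45.18 to 45.26) and 50.7% in pup 3 (50.69 to 50.77). Their mean share was 48.0% ± 3.89, and the 25 most abundant genes took 66.0% ± 1.56.

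**Figure D1:**
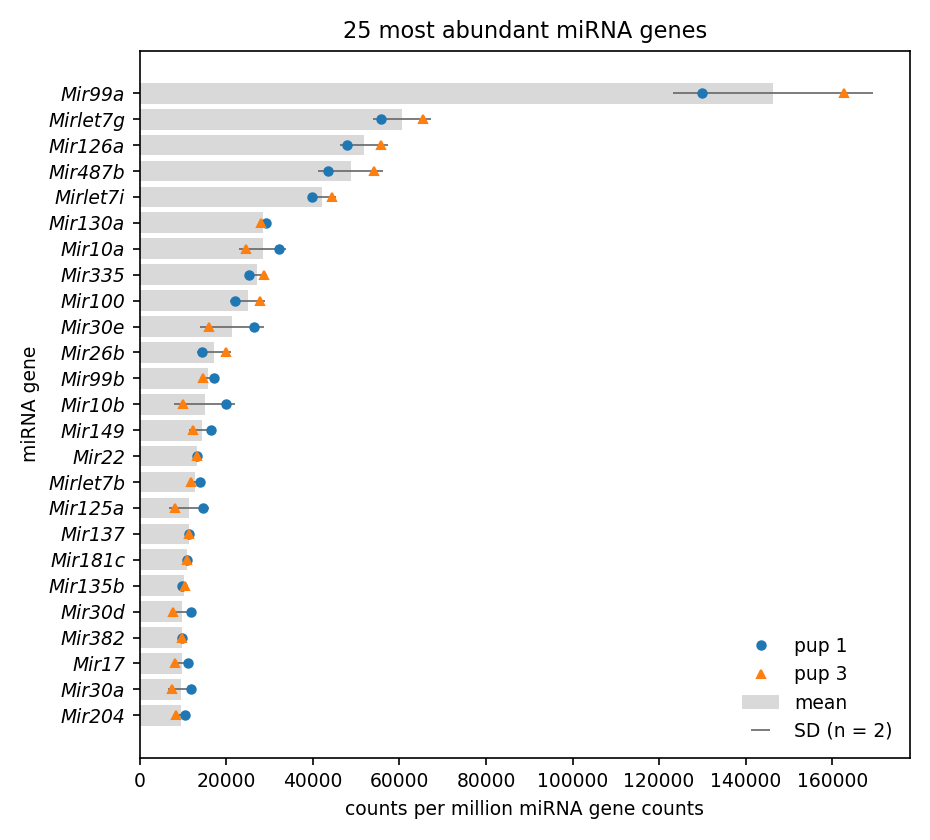
The 25 most abundant of the miRNA genes with an entry of their own, with the level in CPM on the horizontal axis. Bars give the mean of the 2 pups, circles pup 1, triangles pup 3 and lines the SD (n = 2). Mir99a stands at 129913 CPM in pup 1 and 162661 CPM in pup 3, and the next gene, Mirlet7g, averages 60594 CPM.

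These leading genes lay in varied genomic settings (coordinates on GRCm38, the assembly of mm10). Mir99a (ENSMUSG00000065530.1) is at chromosome 16, 77598936 to 77599000, on the plus strand, in an intron of the noncoding gene Mir99ahg. Mirlet7g (ENSMUSG00000065440.1) is at chromosome 9, 106178840 to 106178927, on the plus strand, in an intron of Wdr82. Mir126a (ENSMUSG00000065540.1) is at chromosome 2, 26591357 to 26591429, on the plus strand, over an exon of Egfl7. Mir487b (ENSMUSG00000076219.1) is at chromosome 12, 109727333 to 109727414, on the plus strand, with no annotated host gene on that strand. Mirlet7i (ENSMUSG00000065406.2) is at chromosome 10, 122985640 to 122985724, on the minus strand, over an exon of D630033A02Rik. The others among the 25 most abundant genes were Mir26b, Mir99b, Mir10b, Mir149, Mir22, Mirlet7b, Mir125a, Mir137, Mir181c, Mir135b, Mir30d, Mir382, Mir17, Mir30a and Mir204. They ran from 17107 ± 3881 CPM for Mir26b down to 9449 ± 1556 CPM for Mir204. Genes without an entry of their own are not ranked. Mir376a is one of them, and read from the opposite strand it would lie within this range at 9662 ± 3406 CPM. Of these 25 genes, Mir487b was the one whose precursor shared a 20-base stretch with another miRNA precursor, so its level is uncertain.

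In all, 407 of the 1973 miRNA genes (20.6%) reached 2 CPM in both pups, the level set for detection. Pup 1 had 435 genes at that level and pup 3 had 421, with 28 reaching it in pup 1 alone and 14 in pup 3 alone. At least 1 count in either pup was seen for 768 genes, and 1205 genes had 0 counts in both. Detected genes were nearly all among those with a Mir symbol, 403 of 1051, against 4 of the 922 genes with other names. Levels covered a wide range: 97 genes reached 1000 CPM in both pups and 18 reached 10000 CPM. By annotation, 199 detected genes lay in an intron of a host gene on the same strand, 166 of them in a protein-coding host. A further 87 overlapped an exon and 121 had no host gene on their strand.

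The miR-99, miR-100 and miR-125 genes took 20.3% ± 2.09 of own-strand counts, and all 6 were detected. Shares of families leave out reads that matched several genomic places, so they do not rank families with many copies, such as let-7. Besides Mir99a they included Mir100 at 24926 ± 3980 CPM, Mir99b at 15870.5 ± 1892 CPM and Mir125a at 11357 ± 4682 CPM. Mir99b and Mir125a lie within 1 host, Spaca6, on chromosome 17. The let-7 family took 13.3% ± 0.730, with all 10 counted genes detected. Its 4 most abundant members were Mirlet7g, Mirlet7i, Mirlet7b at 12884 ± 1559 CPM and Mirlet7d at 7836 ± 303 CPM. Mirlet7e and Mirlet7f-1 had no entry of their own and are not in this share.

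The maternally expressed miRNA genes of the Dlk1-Dio3 imprinted region on chromosome 12 contributed 13.4% ± 0.673 of counts. Of the 49 that were counted, 44 were detected, and 3 had 0 counts in both pups. The detected members span positions 109563692 to 109747960. Mir487b led them, followed by Mir382 at 9816 ± 50.7 CPM, Mir434 at 9339 ± 588 CPM and Mir127 at 8341 ± 182 CPM. Mir376a, Mir409, Mir380 and Mir299a lie in the same span without an entry of their own, so the share and order leave them out. Read from the opposite strand, they averaged 9662, 4634, 2400 and 631 CPM (chosen after their values were seen). Of the 44, 20 averaged at least 1000 CPM and 9 averaged under 100 CPM. By annotated host, 12 lay in Mirg, 2 in Rian and 1 in Meg3, all noncoding genes of the region, and 29 in none of these.

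**Figure D2:**
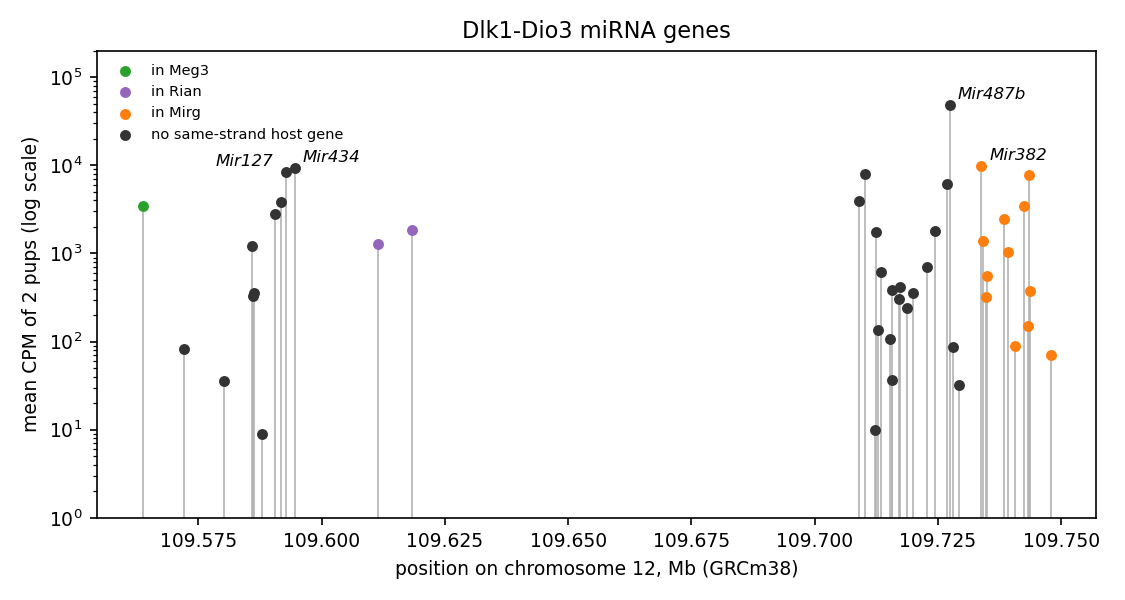
Mean level of the 44 detected miRNA genes of the Dlk1-Dio3 region (vertical axis, log scale, CPM averaged over 2 pups) against their position on chromosome 12 in GRCm38. Colours give the host gene annotated on the same strand, and Mir487b is the highest point at 48749.7 CPM.

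Neuronal miRNA genes, a list fixed for their known enrichment in neurons, made up 6.54% ± 0.576 of counts, and 28 of 32 were detected. The most abundant were Mir149 at 14438 ± 3020 CPM, Mir137 at 11351 ± 16.5 CPM, Mir135b at 10189.9 ± 514 CPM and Mir129-2 at 3695 ± 381 CPM. Mir129-2 is a multi-copy gene, as are Mir124a-1, Mir128-1 and Mir138-1 of the same list. Their reads at several genomic places are left out, so the share does not rank neuronal miRNAs against other lists. The miRNAs linked to neuronal activity took 2.03% ± 0.0475 with all 7 detected. Mir181c had 11025 ± 6.04 CPM among them, Mir379 3963 ± 352 CPM, Mir132 2324 ± 63.7 CPM and Mir134 1396 ± 50.3 CPM. The Hox-linked genes, which lie in the Hox clusters that pattern the hindbrain and spinal cord, took 4.38% ± 1.24 with 5 of 6 detected. Mir10a, on chromosome 11, had 28396 ± 5365 CPM and Mir10b, in an intron of Hoxd3, had 14983 ± 6974 CPM. Mir615, in an intron of Hoxc5, followed at 366 ± 86.1 CPM and Mir196b at 17.6 ± 2.47 CPM. Mir218-2 and Mir218-1, hosted by the axon guidance genes Slit3 and Slit2, were low at 169 ± 19.9 and 39.5 ± 8.19 CPM. Reads of these 2 copies can match both genes.

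The choroid plexus and ependyma list took 1.81% ± 0.130 with all 7 genes detected, led by Mir204 and by Mir449a, a miRNA of multiciliated cells, at 4489 ± 632 CPM. Mir34c had 3932 ± 325 CPM and Mir34b 238 ± 43.5 CPM. The oligodendrocyte list, which shares Mir138-1 and Mir138-2 with the neuronal list, took 0.404% ± 0.162 with all 5 detected. In it, Mir219a-2 stood at 842 ± 51.8 CPM and Mir338 at 752 ± 33.6 CPM, while Mir138-1 and Mir138-2 had 1425 ± 923 and 901 ± 610 CPM. Of these, all but Mir338 share a 20-base stretch with another miRNA precursor, so their counts can leave out reads at several genomic places. The miR-183 sensory cluster took 0.264% ± 0.108, with Mir182 at 1376 ± 975.4 CPM, Mir183 at 858 ± 50.5 CPM and Mir96 at 403 ± 50.7 CPM.

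Of the vessel and connective tissue list, 9 of 10 genes were detected, and these took 7.40% ± 0.646 of counts. Mir126a made up most of that share. Mir143 had 8242 ± 1585 CPM, Mir23a 7488 ± 835 CPM and Mir140, over an exon of Wwp2, 5616 ± 155 CPM. Blood lists were low. The erythroid list took 0.0403% ± 0.0135, with Mir451a at 360 ± 144 CPM, Mir144 at 21.9 ± 8.22 CPM and Mir486 at 21.3 ± 0.971 CPM. The leukocyte and microglia list took 0.0874% ± 0.0204, with Mir150 at 394 ± 133 CPM, Mir223 at 204 ± 11.0 CPM, Mir146 at 151 ± 31.4 CPM and Mir155 at 121 ± 29.7 CPM. Mir142 had no entry of its own, so this share and order leave it out. Read from the opposite strand, Mir142 averaged 375 ± 86.3 CPM (chosen after its value was seen). The epithelial list took 0.0877% ± 0.0136 with all 7 detected, led by Mir203 at 693 ± 113 CPM, Mir429 at 74.4 ± 23.1 CPM, Mir205 at 44.8 ± 4.40 CPM and Mir200b at 32.9 ± 4.72 CPM.

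Lists for tissues outside the brain were also partly detected. The muscle list took 0.0232% ± 0.00274 with 5 of 9 genes detected and 3 at 0 counts in both pups. Mir206 had 164 ± 11.1 CPM, Mir208b 44.9 ± 15.7 CPM, Mir499 11.1 ± 0.151 CPM and Mir208a 5.16 ± 1.63 CPM, the last 3 in introns of myosin heavy chain genes. The liver, pancreas and gut list took 0.230% ± 0.0117 with 7 of 9 detected. It was led by Mir217 at 1031 ± 145 CPM, Mir375 at 462 ± 4.77 CPM, Mir216b at 338 ± 48.6 CPM and Mir216a at 169.9 ± 11.1 CPM. The pluripotency list took 0.0355% ± 0.00570 with 6 of 12 detected and 1 at 0 counts in both pups. Its highest members were Mir302a at 133 ± 32.2 CPM, Mir302d at 117 ± 8.72 CPM, Mir302b at 74.3 ± 10.5 CPM and Mir302c at 17.8 ± 4.99 CPM.

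Among the remaining families, the miR-30 genes took 4.12% ± 1.35 with all 6 detected, led by Mir30e, Mir30d at 9837 ± 2958 CPM, Mir30a at 9566 ± 3143 CPM and Mir30b at 472 ± 56.2 CPM. The proliferation-linked miR-17-92 cluster and its paralogs took 2.76% ± 0.280 with 14 of 15 detected. Mir17 had 9681 ± 2034 CPM, Mir93 5029.8 ± 676 CPM, Mir106b 4768 ± 613 CPM and Mir20a 4004 ± 372 CPM. Mir93 and Mir106b lie in Mcm7, which encodes a replication factor. The miR-181 family took 2.10% ± 0.0982 with all 6 detected, led by Mir181c, Mir181a-1 at 4738 ± 672 CPM, Mir181d at 4464 ± 1097 CPM and Mir181b-2 at 638 ± 524 CPM. Mir181a-1 and Mir181b-2 share a 20-base stretch with another miRNA precursor, so the order within this family is uncertain. The miR-29 family, whose miRNAs increase as neurons mature, took 0.113% ± 0.00767 with all 4 detected. Mir29c had 569 ± 38.0 CPM and Mir29a 552 ± 42.3 CPM, against 7.56 ± 0.263 CPM for Mir29b-2 and 4.41 ± 3.28 CPM for Mir29b-1. Mir29c, Mir29b-2 and Mir29b-1 share a 20-base stretch with another miRNA precursor, so their counts can leave out reads at several genomic places. The gap within the family thus does not measure a difference in expression alone. The rodent-specific cluster in an intron of Sfmbt2 took 0.516% ± 0.0264, led by Mir467d at 1956 ± 166 CPM, Mir467e at 1539 ± 145 CPM, Mir467c at 798 ± 104 CPM and Mir669o at 337 ± 74.3 CPM. Only 8 of its 34 counted genes were detected and 18 had 0 counts, in a cluster of near-identical copies.

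**Figure D3:**
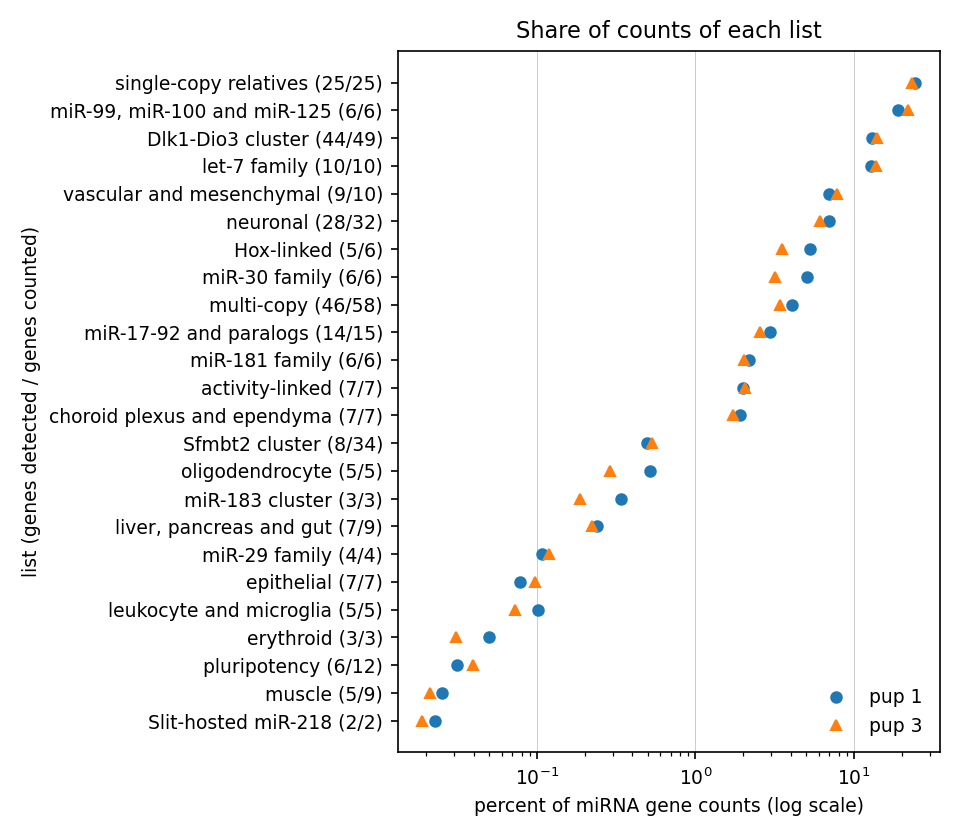
Percent of miRNA gene counts taken by each of the 24 lists (horizontal axis, log scale) in pup 1 (circles) and pup 3 (triangles). Each row names a list with the number of its genes detected in both pups over the number counted, and genes may be in several lists. Shares run from 0.0209% for the Slit-hosted miR-218 genes to 23.8% for the single-copy relatives (means of 2 pups).

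Whether listed genes were detected more often than other miRNA genes was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. This held for 23 lists, and every member was detected in 14. The 23 included the erythroid, muscle and liver, pancreas and gut lists, so passing does not mark miRNAs of the hindbrain. The other genes include those without a Mir symbol, 922 in all with 4 detected, a background that favours any list of Mir genes. Detection was 89.8% for the Dlk1-Dio3 list against 18.9% for other genes (exact test, adjusted p = 1.65e-24) and 87.5% against 19.5% for the neuronal list (exact test, adjusted p = 2.80e-15). The Sfmbt2 list was the exception, at 23.5% against 20.6% (exact test, adjusted p = 0.670), and against other genes with a Mir symbol, detected more often than it, its exact test adjusted p was 0.0859. At a detection level of 10 CPM, the miR-29, muscle and pluripotency lists missed the threshold, with exact test adjusted p of 0.127, 0.159 and 0.117, and 20 lists passed. The miR-218 list, with 2 members, had an exact test adjusted p of 0.0443, but of 0.0559 at 1 CPM, 0.0594 at 5 counts and 0.0506 without pup 3. Against other genes with a Mir symbol only, a background chosen after seeing the data, 18 lists passed. The erythroid, muscle, pluripotency, miR-183 and miR-218 lists then missed the threshold, with exact test adjusted p of 0.0673, 0.330, 0.552, 0.0673 and 0.160. Genes of a list are not independent replicates, so these p-values describe the lists only.

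The 2 hindbrains had closely matching profiles. Across the 768 genes with a count, Pearson's r of log2(CPM + 1) was 0.994 and Spearman's rho 0.953. Across the 407 detected genes they were 0.991 and 0.986. These correlations are across genes, which are not independent replicates. After scaling by TMM, the median absolute log2 difference of detected genes was 0.27, the 90th percentile was 0.81, and 382 of them (93.9%) differed by less than 2-fold. Mir181c, Mir137, Mir22 and Mir382 differed least among the 25 most abundant genes in CPM, while Mir10b had 19914.5 CPM in pup 1 and 10051 CPM in pup 3. The biological coefficient of variation, estimated by edgeR over 412 genes, was 0.233 (bootstrap interval over genes 0.211 to 0.256). The counts of the libraries differed by more than counting error, with a chi-square per tested gene of 437, a value that does not separate 2 animals from 2 preparations of 1 RNA.

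**Figure D4:**
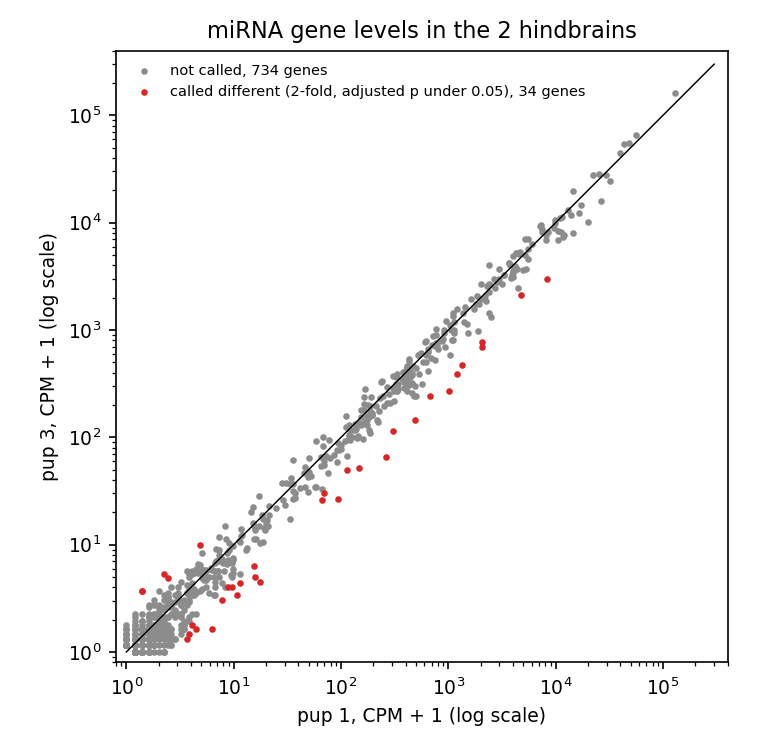
Level of each of the 768 miRNA genes with a count in pup 1 (horizontal axis) and pup 3 (vertical axis), as CPM + 1 on log scales. Red points are the 34 genes called different and the line marks equal CPM. Most red points lie below the line.

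A small set of genes differed between the 2 libraries by at least 2-fold and by more than counting error, and most of these were lower in pup 3. An exact binomial test per gene, Benjamini-Hochberg adjusted over 508 tested genes, called 34 genes, 29 lower and 5 higher in pup 3. The split depended on the scaling, with 25 lower and 8 higher with DESeq2 size factors and 38 lower and 4 higher on library totals. Of the 17 called genes that averaged at least 10 CPM, all were lower in pup 3. The 5 higher genes, Mir3080, Mir6951, Mir3094, Mir1929 and Mir2137, each averaged under 10 CPM and are named after their values were seen. The test compares these libraries, not conditions, and its p-values hold no estimate of the spread between animals or preparations. Simulated pairs of libraries with no changed gene and the estimated spread between pups gave a median of 22.5 calls, and 15 to 31 in 20 runs. The 34 calls lay above that range. But the spread was estimated from these same 2 libraries without leaving out called genes, so the runs are no independent reference. At any fold, 242 genes passed the adjusted p, 121 in each direction. When only genes with 100 or more counts were tested, 18 genes were called, all lower in pup 3.

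The 5 largest differences among called genes of at least 10 CPM were in Mir702, Mir181b-1, Mir181b-2, Mir103-2 and Mir668. Their log2 differences are on TMM scaling and so are smaller in size than the CPM, which are on library totals, would give (-2.02 for Mir702 on totals). Mir702 (chromosome 5, 136991433 to 136991541, over an exon of Plod3) had 263 CPM in pup 1 and 64.1 CPM in pup 3, a log2 difference of -1.88 with a counting error (SE) of 0.08 (exact binomial test, adjusted p = 8.19e-138). Mir181b-1 (chromosome 1, 137966639 to 137966718, over an exon of A430106G13Rik) had 16.5 and 3.53 CPM, a log2 difference of -1.83 (SE 0.35, exact binomial test, adjusted p = 1.01e-10). Mir181b-2 (chromosome 2, 38853830 to 38853918, no host on its strand) had 1008 and 267 CPM, a log2 difference of -1.77 with an SE of 0.04. Mir103-2 (chromosome 2, 131288052 to 131288137, in an intron of Pank2) had 92.7 and 25.8 CPM, a log2 difference of -1.67 (SE 0.13, exact binomial test, adjusted p = 1.11e-42). Mir668 (chromosome 12, 109734732 to 109734797, over an exon of Mirg) had 492 and 145 CPM, a log2 difference of -1.61 (SE 0.06, exact binomial test, adjusted p = 3.37e-206). Mir181b-1, Mir181b-2 and Mir103-2 share a 20-base stretch with another miRNA precursor, so their counts leave out reads that match both copies.

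By list, 13 of 51 tested multi-copy genes were called lower in pup 3, against 29 of all 508 tested genes. So were 4 of 31 neuronal genes (Mir138-1, Mir138-2, Mir124a-1 and Mir124a-3) and 2 of 45 Dlk1-Dio3 genes (Mir541 and Mir668). The let-7 list had 2 of 10 (Mirlet7c-2 and Mirlet7a-1), the miR-181 list 2 of 6 (Mir181b-1 and Mir181b-2) and the oligodendrocyte list 2 of 5. The miR-17-92, miR-29 and miR-183 lists had 1 gene each, Mir19b-2, Mir29b-1 and Mir182. The other 15 lists had 0, and no listed gene was called higher. The lists overlap, and the 16 called genes in any list were the 13 multi-copy genes with Mir541, Mir668 and Mir182. Calls in the neuronal, let-7, miR-181, oligodendrocyte, miR-17-92 and miR-29 lists were thus all of multi-copy genes. Their counts leave out reads at several genomic places. The count adjusted over the list alone equalled that over all genes tested in each of the 24 lists. Genes in this paragraph that the naming rule does not cover were chosen after their values were seen. The 2 oligodendrocyte genes were Mir138-1 and Mir138-2, both copies of a single mature miRNA and both also neuronal, while Mir219a-2 and Mir338 were not called. Mir219a-2 too shares a 20-base stretch with another miRNA precursor, so its count can also leave out reads at several genomic places.

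The median shift of each list between the pups was set against 10000 random lists of equal size and matched mean level. On library totals, the median over all detected genes was -0.14 (log2, pup 3 minus pup 1). With TMM it was -0.01 and with DESeq2 size factors 0.08. The epithelial list lay 0.43 above the overall median (percentile 98.5 of random lists) and the pluripotency list 0.36 above it (percentile 99.0, or 95.7 after a GC correction chosen after seeing the data). The miR-181 list lay at -0.37 relative to it (percentile 1.29) and the multi-copy list at -0.17 (percentile 0.310). The remaining 20 lists lay within the central 95% of random lists. With 24 lists looked at, these percentiles describe the 2 libraries and are not tests.

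Genes whose mature miRNA is made by several copies lay far below relatives made by a single gene in own-strand counts. Such counts leave out reads at several genomic places, so the gap does not measure a difference in expression alone. The 58 multi-copy genes had a median of 119 CPM and the 25 single-copy relatives a median of 4464 CPM. The difference of medians was -5.21 in log2(CPM + 1) (permutation test with 100000 resamples, two-sided, p = 0.00044). All 58 multi-copy precursors, and 3 of the 25 single-copy ones, shared a 20-base stretch with another miRNA precursor. The multi-copy list took 3.74% ± 0.451 of counts with 46 genes detected, led by Mir181a-1, Mir129-2, Mir128-1 at 3587 ± 457 CPM and Mirlet7f-2 at 2921 ± 328 CPM. The single-copy list took 23.8% ± 0.709, led by Mirlet7g, Mirlet7i, Mir30e and Mir26b. Reads that matched several genomic places, which the tables give to no gene, numbered 4601400 in pup 1 and 5639848 in pup 3. These were 37.9% and 39.4% of the reads in each table.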

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

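The tests of opposite-strand reads, the test of other cell types and the GC correction's counts of calls were chosen only after the data were seen, and the other tests in this part before their results. An exception is the Fisher's exact test of shared sequence among called genes, for which no rule was set beforehand.

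Reads on the opposite strand of a gene, which the comparisons leave out, exceeded its own-strand reads in both pups at 11 genes. In sum over the pups they numbered 110893 over Gm25252, 74421 over Gm25927, 50857 over Gm24321, 40715 over Gm25301, 39876 over Gm24083, 27421 over Gm25750, 13340 over Mir497b, 7047 over Mir299b, 4260 over Mir142b, 1334 over Gm24111 and 810 over Gm25641. GENCODE M21 annotates on that other strand Mir376a, Mirlet7e, Mir409, Mir378a, Mir191, Mir380, Mir497, Mir299a, Mir142, Mirlet7f-1 and Mir9-1, in the same order, none with an entry of its own. Read as those genes, Mir376a would stand at 9662 ± 3406 CPM (n = 2) and Mirlet7e at 6702 ± 285 CPM. These genes were chosen after their values were seen.

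Loss of strand information would put opposite-strand reads on genes everywhere. Over the 301 genes with 100 or more counts and no such overlap, the median opposite-strand share was 0%, which argues against it. Of all opposite-strand counts, 99.9% lay in the 32 genes overlapped by a miRNA gene on the other strand that has no entry, a value in line with reads of those missing genes being counted against their antisense neighbours. No biological explanation was tested.

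Reads that matched several genomic places, another part of the tables outside the comparisons, numbered 10241248 in both pups together. Multi-copy genes stood below single-copy relatives by -5.21 in log2. To lift the 57 multi-copy genes below the single-copy median of log levels up to it would take 2433400 reads, and the reads at several places are 4.21 times that number. These reads are thus enough to account for the gap, which is consistent with undercounting of copies, but they also include reads of other repeated sequence, so how many belong to these miRNAs stays open. Mir124a-1, Mir124a-2 and Mir124a-3, copies of the neuronal miR-124, had 9.44, 1.70 and 2.05 CPM, and Mir9-2 had 1.94 CPM, but Mir9-3 had 462 CPM and Mir125b-1, Mir125b-2, Mir101b and Mir92-1 had 2537, 2520.4, 2362 and 1309 CPM, so multi-copy genes were not low alike (examples chosen after their values were seen).

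The 34 genes called different between the libraries were weighed as a further pattern. GC content as the whole cause is argued against, since 29 genes were called after a linear GC trend was removed (-0.12 in log2 per 10% GC, r = -0.217 and rho = -0.238 across 317 genes), and 28 of these were among the 34. A different share of blood, immune, muscle, vascular, epithelial or choroid plexus cells stays open. Those lists held 0% of the called genes, but the exact 95% upper bound of 10.3% includes the 7.28% of tested genes. Relative to the overall median, the epithelial list lay at 0.43 (percentile 98.5 of random lists) and the leukocyte list at -0.28 (percentile 6.945). The erythroid, muscle, vascular and choroid plexus lists lay at 0.23, 0.006, -0.06 and -0.11 (percentiles 87.3, 64.4, 36.6 and 21.5). The leukocyte gene Mir142, read from the opposite strand, went against its list, with 314 CPM in pup 1 and 436 CPM in pup 3. Of the called genes 44.1% share a 20-base stretch with another precursor (15 genes, exact 95% interval 27.2 to 62.1), against 20.3% of all tested genes, called ones included. Called genes shared such a stretch more often than the other tested genes (Fisher's exact test, p = 0.00128). Genes that share sequence are thus over-represented among the calls, but whether they are the main part cannot be told from 34 genes. Differences between the animals, such as sex, stay open and untested.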

How the results depend on the processing

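The GC correction, the Mir-symbol background, the groups by shared sequence and the reassigned opposite-strand reads were chosen after seeing the data. The mean share of the top 10 genes was 41.1% without Mir99a in the total, a change that follows from leaving out the most abundant gene. Pearson's r was 0.9913 with a pseudocount of 0.5 CPM, 0.9955 with 5 CPM, 0.9958 over all annotated genes and 0.9911 over detected genes, where rho was 0.9415 and 0.9861 in the last 2 cases. Over all annotated genes, the 1205 genes with 0 counts in both pups enter as tied values, and the detected set leaves out genes of low counts. How far each change moves r and rho was not tested. Calls numbered 18 with a minimum of 100 counts, 18 lower and 0 higher, because fewer genes were tested. At any fold they numbered 242, 121 lower and 121 higher, because the fold limit was dropped. With DESeq2 size factors 8 genes were called higher, and the share of calls lower in pup 3 was 75.8% against 85.3% with TMM and 90.5% on library totals. With 1 pup left out, 421 to 435 genes were detected, the top 10 share was 45.2% to 51.1%, 22 to 23 lists passed and the multi-copy difference was -5.25 to -5.13. Other alternatives gave 307 to 471 detected genes, 29 to 42 calls, a coefficient of variation of 0.231 to 0.251 and a multi-copy difference of -5.61 to -4.95. The 5 named differences stayed called in 30 of 30 checks. Of the checks of list detection 157 kept their call and 11 lost it, and of those of list shifts 95 kept it and 1, the pluripotency list after GC correction, did not (percentile 95.7). The 5 named differences, the multi-copy difference and the 4 list shifts outside the central 95% of random lists kept their sign. Medians of lists inside it could change sign, as for the erythroid list (0.09, or -0.03 with counts regardless of strand) and the miR-29 list (0.04, or -0.01 after GC correction). Agreement, spread, calls and shifts need both libraries, so leaving out a pup gave no value for them. No paired analysis was possible because there is 1 group. Depth, the fold limit and the pseudocount limit which changes can be called. With counting error only, 77% of simulated 3-fold changes over the 508 tested genes were called.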

Other observations

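The comparison of neighbouring genes after GC correction was chosen only after the data were seen, and the other tests in this part before their results. Groups of miRNA genes outside the fixed lists, chosen after their values were seen, held sizeable shares. Htr2c, the gene of the serotonin receptor 2C on the X chromosome, hosts 7 counted miRNA genes in its introns, of which 6 were detected. Together they took 0.767% ± 0.0998 of counts (n = 2). Mir1298 had 6271 ± 1002 CPM, Mir448 713 ± 9.57 CPM and Mir1264 636 ± 12.1 CPM, while Mir764 and Mir1912 had 30.4 ± 6.66 and 16.4 ± 3.83 CPM. Elsewhere on the X chromosome, Mir322 and its 10 kb neighbourhood (53047997 to 53054349, 7 genes, all detected) took 0.967% ± 0.123. Mir322 had 8438 ± 1515 CPM and Mir351, Mir542 and Mir503 had 811 ± 312, 214 ± 31.9 and 144 ± 18.6 CPM. The 5 genes in Clcn5 took 0.317% ± 0.000399 together, although Mir362 alone among them was called lower in pup 3.

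The imprinted Gnas region on chromosome 2 holds Mir296 and Mir298, at 3004 ± 8.81 and 3785 ± 371 CPM and 0.679% ± 0.0362 of counts together (chosen after their values were seen). Within the pluripotency list, Mir302a, Mir302b, Mir302c and Mir302d took 0.0343% ± 0.00565 of counts. The 7 counted genes from Mir290a to Mir295 on chromosome 7 took 0.00122% ± 4.81e-05, and 2 of them were detected, Mir294 at 5.11 ± 0.0238 CPM and Mir293 at 4.38 ± 0.147 CPM. Mir342, in an intron of Evl, was the most abundant gene called different, with 8391 CPM in pup 1 and 2982 CPM in pup 3.

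A hypothesis set before the result was seen was that miRNA genes within 10 kb of each other, which may be processed from 1 transcript, have closer levels than random pairs. Over 118 neighbouring pairs of 167 detected genes, the median absolute difference in mean log2(CPM + 1) was 2.48, against 3.81 for randomly reassigned levels (permutation test, one-sided, p = 0.0003), which is in line with it. The same pairs did not move together between the pups more than random pairs. Their median absolute difference in log2 pup difference was 0.39, against 0.41 for random pairs (permutation test, one-sided, p = 0.338), and 0.40 against 0.39 after a linear GC trend was removed (permutation test, p = 0.536). A shared transcript is thus a candidate explanation for the levels only, and pairs that are similar in sequence could contribute too, which was not tested.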
